A study of Oryza sativa with 4 samples.

How the data were processed

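Transcript levels were measured in coleoptiles of rice (Oryza sativa cv Nipponbare) with the Affymetrix Rice Genome GeneChip, a one-colour array on which each transcript is read by a set of short probes. Per the labels, seeds germinated for 4 days at 28 °C in the dark, either in air, which the labels call the control, or in an anaerobic chamber with N2 and H2 at 90 to 10. There were 2 arrays of aerobic and 2 arrays of anoxic coleoptiles. The primary leaf was cut out of the aerobic coleoptiles before RNA extraction, and per the labels anoxic coleoptiles hold no such leaf, so the cutting itself went with the group. Groups and replicate numbers came from the sample titles. The labels do not say whether the replicates of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be partly technical.

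The deposited values were 1 normalized intensity per probe set and array on a linear scale, and per the labels' list of processing tools they were made with GCRMA, a background correction and normalization that models the base composition of probes. The version of GCRMA and its settings are not given in the sources used here. The values ran from 2.25 to 18694, and the array medians lay between 7.36 and 7.55, so no further scaling was applied. The base-2 logarithm was taken after adding a pseudocount of 1. Fold changes are therefore on the log2(intensity + 1) scale, which understates the change of dim probe sets. For arrays, no depth applies, and the number of arrays limits the precision.

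Of 57381 probe sets, 187 control probe sets (123 Affymetrix and 64 reporter sequences) were left out of the tests. The remaining 57194 were named through the platform's annotation, which can be old: 22436 had 1 gene, 95 had several and were left unnamed, and 34663 had no gene in that table. All 17905 genes were found in the RefSeq gene table of assembly ASM3414082v1, which was used for names only, and 2458 of them carried a symbol or synonym beyond a locus number. Probe sets with a mean of at least 4 over the 4 arrays on the log2 scale were tested, which left 18826. The reporter probe sets, which read sequences used in transgenic plants, gave a background: their median was 2.74 in aerobic and 2.75 in anoxic arrays, and the highest group mean of any of them was 4.05. Where the dimmer group of a called gene lay at or below 4.05, the change is given as an at least N-fold bound, the brighter group's mean against 4.05.

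Anoxic and aerobic arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), with Benjamini-Hochberg adjustment over the probe sets tested. A probe set was called at an adjusted p under 0.05 with an absolute log2 change of at least 1. The fit had 2 residual degrees of freedom, to which eBayes added 2.34. With 2 arrays against 2, an exact permutation test of a single gene could not pass any usual threshold, so the gene-wise p-values rest on limma's pooling of the spread across probe sets. A gene was represented by its brightest tested probe set by the mean over the 4 arrays. Of 12291 genes tested, 1473 had several tested probe sets, and for 11 genes these were called in opposite directions.

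Gene lists were compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the 33 lists that had at least 3 tested genes; camera with an estimated correlation and fry were alternatives. The list topics and the key genes were written before the data were examined as patterns for gene descriptions. The tables used here hold symbols and no descriptions, so the patterns were rewritten for symbols and synonyms, before any gene's values by group were looked at. This matched 31 of the planned lists, and 5 more lists were added at that point, for jasmonate, metallothionein, endoplasmic reticulum folding, chitinase and sugar transporter genes. The lists hold only genes with a symbol, and a pectin enzyme list and the key genes ADH1 and EXPB12 were not matched and are not analysed here. Named genes were chosen by a rule that was also set beforehand: the key genes, the 8 largest rises and 8 largest falls among called genes with a symbol whose arrays did not overlap between groups, and per list up to 2 called genes with the largest rise and 2 with the largest fall, or the gene with the smallest p where none was called. Genes named outside this rule were chosen after their values were seen: further members given as examples of a list, family members by symbol, and every gene of the small heat shock plot.

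The steps were tested on simulated data made from the real means of the probe sets. Spreads were drawn from limma's fitted variance model, independently for each probe set. The simulation thus shares limma's assumptions and cannot show how correlated genes affect the list test. With 200 of 18826 probe sets changed, limma called 66 of 100 with a log2 change of 3, 0 of 100 with a change of 1.5, and 4 unchanged ones, while the list test called the 1 shifted list and 0 of the others among 20. With as dense a change as the data showed, limma called 2908 of 3012 probe sets with a change of 3, 2529 of 3012 with a change of 1.5, and 106 of 12802 unchanged ones. The list test, with its 1 list shifted by 1 log2 unit, was run only with 200 probe sets changed. How it behaves with a dense change was therefore not checked.

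Alternatives covered the scale (quantile normalization, equal array medians), the filter on low values (none, or a mean of at least 6), a floor at 5, pseudocounts of 0 and 16 on the same probe sets, the variance model, the fold threshold, the replicate number as a block, leaving out each array, and, for lists, the correlation, the test and the choice of probe set.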

Results

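The data compared the transcripts of 4-day-old rice coleoptiles, the sheath that encloses the shoot of a germinating grass, after germination in air or without oxygen in the dark. Each group had 2 arrays. Over the 18826 tested probe sets, replicate arrays correlated with r = 0.973 in aerobic and 0.968 in anoxic coleoptiles, against 0.687 to 0.698 between groups (Pearson, across probe sets, which are not independent replicates). The array medians of the deposited intensity lay between 7.36 and 7.55. The SD of the log2 difference was 0.47 and 0.52 between replicates and 1.59 to 1.61 between groups.

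Germination without oxygen came with a large change in both directions. By limma, 6036 probe sets (32.1%) passed, 3015 of them higher and 3021 lower in anoxic coleoptiles. Among them, 401 were at least 8-fold higher and 815 at least 8-fold lower. Both anoxic arrays lay on the same side of both aerobic arrays for 75.7% of tested probe sets, where chance gives 33.3%. On the level of genes, 1958 of 12291 rose and 2212 fell. For 5 lists the median and the mean of the log2 changes differed in sign: starch breakdown (-0.13 and 1.84, tested up), sucrose and trehalose (0.16 and -0.08, up), gibberellin (0.03 and -0.30, down), seed storage (-0.07 and 0.14, up) and sugar transporters (-0.01 and 0.38, up). In 1574 of the called probe sets, the dimmer group lay at or below the brightest reporter probe set.

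All 3 tested genes of ethanol fermentation rose. PDC1 (LOC4339066), a pyruvate decarboxylase that opens the route to ethanol, was at background in air and reached a log2 level of 12.10 ± 0.17 in anoxia (SD, n = 2), at least 265-fold higher (limma, adjusted p = 0.000588). Adh2 (LOC4350054), an alcohol dehydrogenase that makes ethanol from acetaldehyde, rose by 4.83 ± 0.36 log2 units (SE; adjusted p = 0.00245), and PDC2 (LOC4332519), which read 9.97 in air, by 1.82 ± 0.24. Adjusted over the list alone the number was also 3, and the list was shifted up (camera, adjusted p = 0.0131, and adjusted p = 0.477 with an estimated correlation). The call of PDC2 was lost without aerobic replicate 1 (adjusted p = 0.0511), aerobic replicate 2 (0.0619) or anoxic replicate 1 (0.0531).

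Carbohydrate genes went both ways. RAmy3D (LOC4345814), an alpha-amylase that degrades starch, rose from background at least 182-fold (adjusted p = 0.000842), while DPE1, another enzyme of starch breakdown, fell by 1.27 on the log2 scale, and the list of 4 tested genes was not called (adjusted p = 0.912), with 1 higher and 1 lower also when adjusted over the list alone. Among 17 tested genes of the glycolysis list 4 rose and 2 fell (the same numbers when adjusted over the list alone), and the list was shifted up with a median of 0.71 (adjusted p = 0.0386, and adjusted p = 0.697 with an estimated correlation). The rises were PPDK2, a pyruvate, phosphate dikinase that interconverts pyruvate and phosphoenolpyruvate (at least 149-fold), the hexokinase HXK7 (5.16 ± 0.29), the phosphoglucose isomerase PGI-B (1.97) and the glyceraldehyde-3-phosphate dehydrogenase GAPC3 (1.53). The hexokinases HXK5 and HXK6 changed by -1.84 and -2.10. The glycolysis call was lost under quantile normalization (adjusted p = 0.0539), a mean of at least 6 (0.0541) and without aerobic replicate 2 (0.0977). Of 15 sucrose and trehalose genes 3 rose, including the trehalose phosphatases TPP1 (2.08 ± 0.27) and TPP2 (LOC4349333, 2.36 ± 0.36). In the same list 4 fell, including the invertases INV1 (at least 9.75-fold lower) and CIN1. Another trehalose phosphatase, TPP7, was among the falls (2.49-fold lower), and TPP9 was not called. The list was not called (camera, adjusted p = 0.912), and the numbers were the same when adjusted over the list alone. Without aerobic replicate 1 the calls of DPE1, HXK5, TPP1, TPP2 and CIN1 were lost (adjusted p from 0.0642 to 0.141), without aerobic replicate 2 those of DPE1, HXK5, TPP2 and CIN1 (0.0757 to 0.155), and without anoxic replicate 1 those of DPE1 and TPP1 (0.0585 and 0.0541). The key gene SUS1, a sucrose synthase, stood 0.80 ± 0.19 log2 units higher in anoxia, under the fold threshold (adjusted p = 0.0348). Of the other sucrose synthase genes, SUS2 was called (2.13-fold higher) and SUS4 was not.

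In the TCA cycle list, 1 of 14 tested genes passed: PDHE1-A (LOC4330673), a subunit of pyruvate dehydrogenase, fell by 1.77 ± 0.17 on the log2 scale. The list median was -0.44 and the list was not called (adjusted p = 0.0787), with 1 gene passing also when adjusted over the list alone. It was called lower with no filter on mean level (0.00634), with values under 5 set to 5 (0.0233) and by fry (0.0155). Without aerobic replicate 2 the call of PDHE1-A was lost (adjusted p = 0.0509). The alternative oxidase AOX1A differed by 0.12 ± 0.58 (adjusted p = 0.887; -0.68 without anoxic replicate 1) and the cytochrome oxidase subunit COX5c by 0.37 ± 0.17 (adjusted p = 0.156); each was the 1 tested gene of its list. Both tested haemoglobin genes rose (2 also when adjusted over the list alone): NSHB1, a non-symbiotic haemoglobin, by 6.11 ± 0.38 and NSHB2 by 6.17 ± 0.74 log2 units (adjusted p = 0.00184 and 0.00656). The other 2 tested probe sets of NSHB1 also rose but by 2.44 and 2.19 log2 units, so the size of its rise depends on the probe set. NSHB2 rose by 7.24 without aerobic replicate 1 and by 5.10 without aerobic replicate 2. Its call was lost without anoxic replicate 1 (0.0586) or anoxic replicate 2 (0.058).

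**Figure D1:**
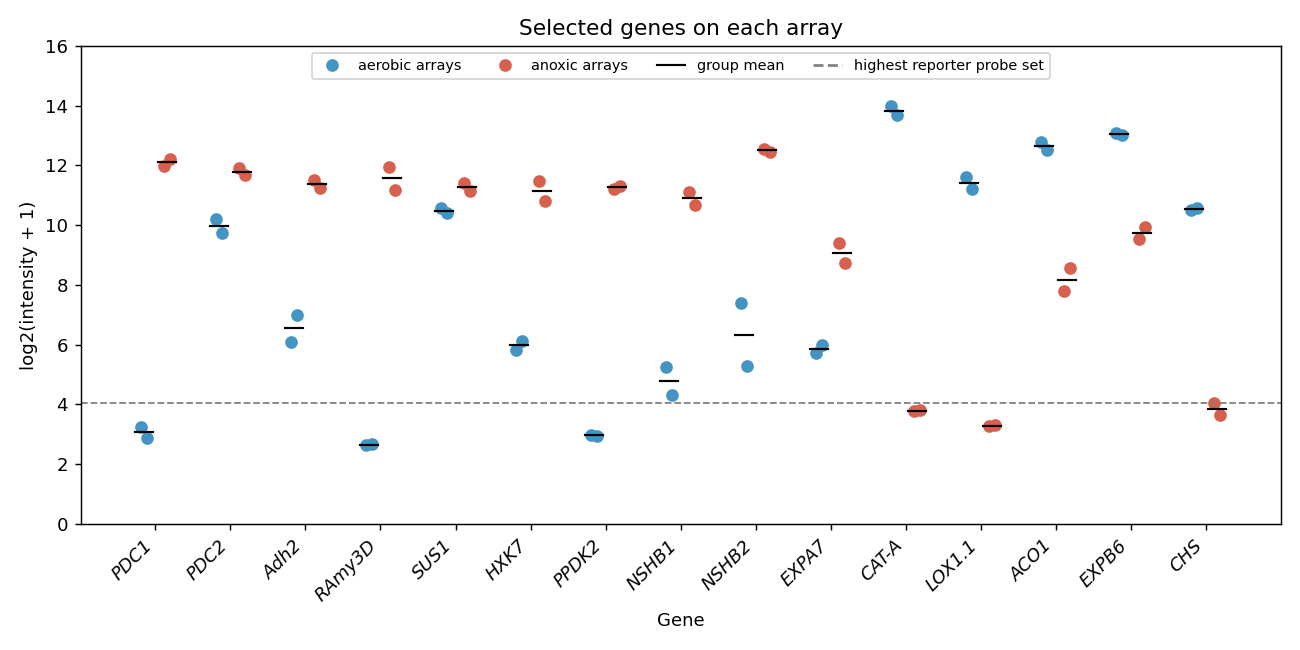
Level of 15 genes as log2(intensity + 1) on each of the 4 arrays, with aerobic arrays in blue, anoxic arrays in red, group means as black bars and the highest reporter probe set as a dashed line at 4.05. PDC1, RAmy3D and PPDK2 lie under the dashed line in air and above 11 in anoxia, and CAT-A, LOX1.1 and CHS have anoxic means under it.

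Cell wall genes went both ways. EXPA7 (LOC4334606), an expansin, a class of proteins that loosen the wall, rose by 3.23 ± 0.29 (adjusted p = 0.00359), and the expansin-like EXLA1 by 2.20 ± 0.25 and EXLA2 by 2.00. EXPB2 fell at least 13.7-fold (8.61-fold without aerobic replicate 2 and 21.9-fold without aerobic replicate 1) and EXPB6 fell by 3.32 ± 0.21. In all, 3 of 15 tested expansin genes rose and 7 fell (4 and 7 when adjusted over the list alone), and the list was not called (median -0.92, adjusted p = 0.252). The calls of EXPA7 and EXLA1 were lost without aerobic replicate 1 (adjusted p = 0.0574 and 0.0689) or aerobic replicate 2 (0.0518 and 0.063). The list of xyloglucan and cellulose enzymes was shifted down, with 14 of 29 genes lower and 3 higher, the same numbers when adjusted over the list alone (median -0.95, camera, adjusted p = 0.00372, and adjusted p = 0.477 with an estimated correlation). Its glucanase genes went both ways, GLU10 at least 4.16-fold lower, GLU11 at -2.97 ± 0.18 and GLU1 higher by 2.12 ± 0.20. In the phenylpropanoid and lignin list 11 of 16 genes fell and 2 rose, likewise when adjusted over the list alone (median -2.39, adjusted p = 0.0105, adjusted p = 0.712 with an estimated correlation, and 0.0841 by fry), a call also lost with a mean of at least 6 (0.0855). The cinnamyl alcohol dehydrogenases CAD8A (-6.63 ± 0.50, its call lost without aerobic replicate 2) and CAD8C (at least 34.0-fold lower) fell, while CAD7 and the cinnamoyl-CoA reductase CCR1 rose from background at least 72.9-fold and 60.2-fold. CAD8A changed by -5.94 without anoxic replicate 2. Without anoxic replicate 1 it was at background in anoxia and at least 104-fold lower. Outside these lists, CHS, the chalcone synthase that opens flavonoid synthesis, was among the 8 largest falls of called genes with a symbol and fell at least 89.5-fold (adjusted p = 0.000739).

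Hormone genes fell in several lists. Of 9 genes of ethylene synthesis and perception 6 fell and 0 rose, also when adjusted over the list alone (median -2.10, adjusted p = 0.00514, and adjusted p = 0.477 with an estimated correlation). Among them were ACO1, whose enzyme makes ethylene from its precursor with oxygen (-4.47 ± 0.32), the receptor gene ERS2 (at least 3.89-fold lower) and EIL1B, a transcription factor of the pathway (adjusted p = 0.000857). With a mean of at least 6 the ethylene and auxin calls were lost (adjusted p = 0.0541 for each). Of 43 auxin response genes 18 fell and 4 rose (19 and 4 when adjusted over the list alone; median -0.92, adjusted p = 0.0352, and adjusted p = 0.477 with an estimated correlation): IAA20 fell at least 7.11-fold and the response factor ARF22 by 2.87, while SAUR39 rose at least 46.7-fold. Of 24 jasmonate genes 21 fell and 0 rose, also when adjusted over the list alone, the smallest p of any list by camera with the preset correlation (median -2.84, adjusted p = 4.26e-08, and adjusted p = 0.624 with an estimated correlation). They covered synthesis, with the allene oxide synthase AOS4 at -5.54 ± 0.17, and all 11 tested JAZ genes, which encode repressors of the response, with JAZ3 at least 49.5-fold lower. JAZ1, JAZ2 (LOC4331833), JAZ4, JAZ5, JAZ6 and JAZ8 lost their calls without aerobic replicate 1 or 2, though they stayed lower. JAZ1 also lost its call without either anoxic array, and JAZ5, JAZ6 and JAZ8 without anoxic replicate 2. The list held lipoxygenases by symbol, whether or not they serve jasmonate synthesis. Of these LOX1.1 fell at least 164-fold. All 19 tested genes of the list other than LOX genes fell. The aerobic coleoptiles of this comparison had been cut to remove the leaf. Of 9 gibberellin genes 1 rose and 3 fell (list adjusted p = 0.66): the receptor gene gid1 rose by 1.43 ± 0.25 and SLR1, the DELLA repressor, fell by 1.90 on the log2 scale (1 and 3 also when adjusted over the list alone). The call of gid1 was lost without any 1 of the 4 arrays (adjusted p from 0.0535 with aerobic replicate 2 left out to 0.0882 with anoxic replicate 1 left out), and that of SLR1 without aerobic replicate 1 (0.0654) or 2 (0.0553). Of 17 cytochrome P450 genes 11 fell and 2 rose, likewise over the list alone (median -2.41, adjusted p = 0.0126, and adjusted p = 0.477 with an estimated correlation); a mean of at least 6 ended this call (0.302). The falls included AOS1, AOS2 and AOS4 of the jasmonate list, and the rises were CYP85A1 (3.91 ± 0.19) and CYP734A6 (1.19), which make and inactivate brassinosteroids. The call of CYP734A6 was lost without aerobic replicate 1 (0.0767), aerobic replicate 2 (0.091) or anoxic replicate 1 (0.0611). Of 7 ERF genes 3 fell, including ERF24 (-3.76 ± 0.29), and of 6 WRKY genes WRKY62 rose and WRKY76 fell; neither list was called (adjusted p = 0.0691 and 0.912), and the numbers were the same when adjusted over the list alone. The ERF list was called without anoxic replicate 2 (0.0274). The call of WRKY62 was lost without aerobic replicate 1 (0.114), aerobic replicate 2 (0.0785) or anoxic replicate 1 (0.0627), and that of WRKY76 without aerobic replicate 2 (0.0571).

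**Figure D2:**
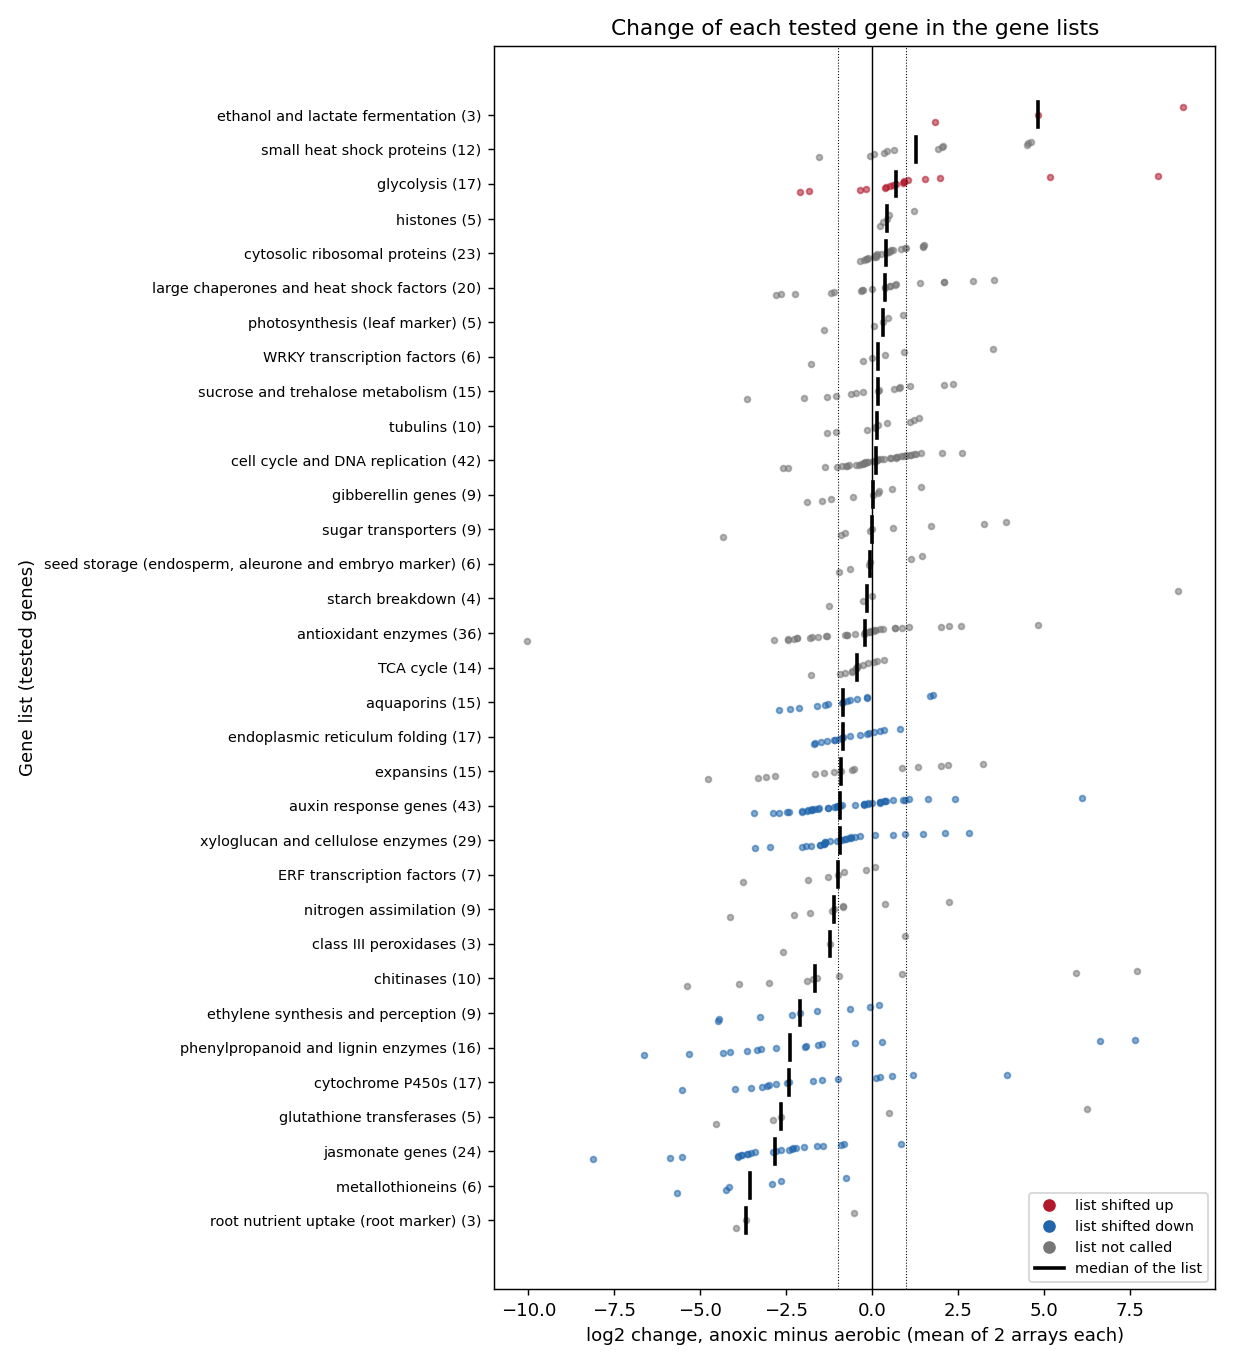
Log2 change, anoxic minus aerobic, of every tested gene of the 33 tested lists, with 1 point per gene, the list median as a black bar and the number of tested genes in parentheses. Red lists were shifted up and blue lists down by camera with the preset correlation, and dotted lines mark the fold threshold of 1. The median of the fermentation genes is 4.83 and that of the jasmonate genes is -2.84.

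CAT-A (LOC4328073), a catalase, had the largest fall among called genes with a symbol whose arrays did not overlap between groups, from a log2 level of 13.83 ± 0.23 in air to background (at least 879-fold lower, adjusted p = 0.000568). Among 36 antioxidant genes 12 fell and 5 rose, the same numbers over the list alone, and the list was not called (median -0.21, adjusted p = 0.128). The cytosolic superoxide dismutase SODCC.2 fell by 2.85 on the log2 scale, the glutaredoxin GRXS2 rose by 2.59 ± 0.21 and the 1-Cys peroxiredoxin R1C-Prx by 4.82 ± 0.41, a call lost without aerobic replicate 1 (0.0527) or 2 (0.0543). Of 5 glutathione transferase genes GSTU1 rose by 6.24 ± 0.25 and 3 fell (1 and 3 also when adjusted over the list alone, list adjusted p = 0.539), with GSTU6 at -4.55 ± 0.21. Of 3 class III peroxidase genes LOC4344277 fell, with 2 lower when adjusted over the list alone (list adjusted p = 0.539). Of 6 metallothionein genes 5 fell and 0 rose, also when adjusted over the list alone (median -3.54, adjusted p = 0.00372, and adjusted p = 0.477 with an estimated correlation), with MT1A at -4.25 ± 0.22 and MT4C at -5.67 ± 0.73, whose call was lost without aerobic replicate 1 (0.0856) or 2 (0.0814). MT4C changed by -4.62 without anoxic replicate 1. Without anoxic replicate 2 it was at background in anoxia and at least 83.4-fold lower.

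Stress chaperones rose in part. Of 12 small heat shock genes 3 rose (2 when adjusted over the list alone), HSP18.1 at least 22.6-fold from background (6.45-fold without anoxic replicate 1 and 79.2-fold without anoxic replicate 2), HSP24.1 by 4.54 ± 0.53 (3.93 without anoxic replicate 1 and 5.15 without anoxic replicate 2) and HSP17.9A by 4.50 ± 0.36 log2 units, and the list was not called (median 1.27, adjusted p = 0.092), though it was without anoxic replicate 2 (median 2.04, 0.00272; median 0.49 without anoxic replicate 1). The calls of HSP18.1, HSP24.1 and HSP17.9A were each lost without aerobic replicate 1 or aerobic replicate 2. In these fits HSP17.9A rose by 4.55 and 4.46 log2 units. Anoxic replicate 1 lay above anoxic replicate 2 for 11 of these 12 genes; HSP18.1 read 10.36 and 6.74 on them. Of 20 large chaperone and heat shock factor genes 4 rose and 3 fell (likewise over the list alone, list adjusted p = 0.799), with the factor HSFB2A at least 5.88-fold higher (3.60-fold without anoxic replicate 1 and 9.63-fold without anoxic replicate 2; call lost without aerobic replicate 1, 0.0948, or 2, 0.0933; its other tested probe set changed by 2.32 log2 units) and HSFA2D at -2.66 ± 0.18. Of 17 genes of protein folding in the endoplasmic reticulum 6 fell and 0 rose, also over the list alone (median -0.85, adjusted p = 0.0386, and adjusted p = 0.477 with an estimated correlation), among them the disulfide isomerase genes PDIL2-1 and PDIL5-1 with -1.69 ± 0.21 and -1.65 ± 0.16. Calls of both genes were lost without aerobic replicate 1 (0.0558 and 0.0518), of PDIL2-1 without anoxic replicate 2 (0.0508) and of PDIL5-1 without aerobic replicate 2 (0.0513). The list's call was lost under quantile normalization (0.0637), a mean of at least 6 (0.0541), and without aerobic replicate 1 (0.0553) or anoxic replicate 1 (0.0667).

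**Figure D3:**
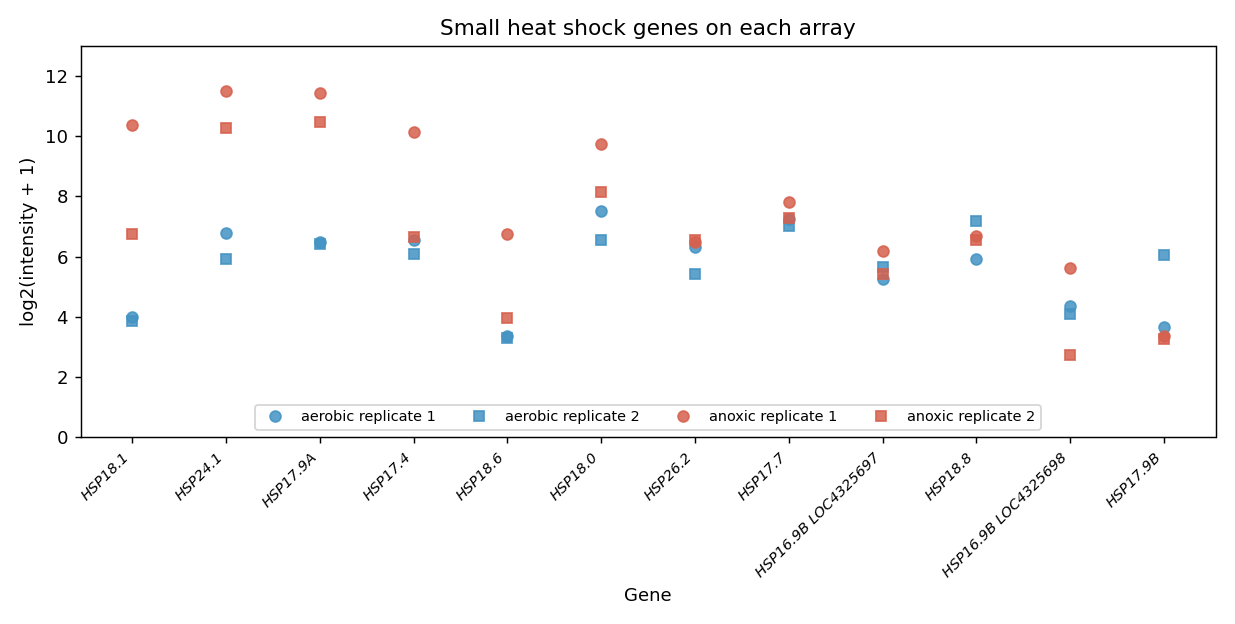
Level of the 12 tested small heat shock genes as log2(intensity + 1) on each array, with aerobic arrays in blue, anoxic arrays in red, replicate 1 as circles and replicate 2 as squares. HSP24.1 and HSP17.9A read above 10 on both anoxic arrays, while HSP18.1 read 10.36 and 6.74.

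Transport and nitrogen genes also differed. Of 15 aquaporin genes 6 fell and 2 rose, likewise over the list alone (median -0.85, adjusted p = 0.0386, and adjusted p = 0.477 with an estimated correlation): PIP1-3 fell by 2.71 and PIP2-2 fell by 2.38 on the log2 scale, and TIP3-1 and PIP2-4 rose by 1.79 ± 0.19 and 1.70 ± 0.35. That call was lost under quantile normalization (0.0637), a mean of at least 6 (0.0541) and without anoxic replicate 1 (0.0675). Without aerobic replicate 1 the gene calls of PIP1-3, TIP3-1, PIP2-4, SWEET1B, NIA1 and LOC4351188 were lost (adjusted p from 0.0528 to 0.154), without aerobic replicate 2 the same but NIA1 (0.0573 to 0.131), and without anoxic replicate 1 that of PIP2-4 (0.0512). Of 9 sugar transporter genes 3 rose, with SWEET1B at least 5.34-fold higher (2.91-fold without anoxic replicate 1 and 9.81-fold without anoxic replicate 2), and the sucrose transporter gene SUT1 fell at least 9.97-fold (3 and 1 also when adjusted over the list alone, list adjusted p = 0.912). Of 9 nitrogen genes 4 fell, with the glutamine synthetase GLN1;2 at -4.14 ± 0.30, and the nitrate reductase NIA1 rose at least 2.34-fold (4 and 1 also when adjusted over the list alone). The nitrogen list was not called (adjusted p = 0.151), though it was without anoxic replicate 1 (0.0192) or 2 (0.0373) and with a mean of at least 6 (0.0422). Of 10 chitinase genes 4 fell, with Cht9 at least 26.2-fold lower, and 2 rose, LOC4351188 by 5.94 ± 0.72 and LOC4351194, which carries the synonym RIXI of a xylanase inhibitor, by 7.69 ± 0.65 (5 and 2 when adjusted over the list alone, list adjusted p = 0.378). LOC4351188 rose by 5.33 and 6.56 without aerobic replicate 1 and 2, and by 5.12 and 6.77 without anoxic replicate 1 and 2. LOC4351194 rose by 6.77 without aerobic replicate 1. Without aerobic replicate 2 it was at background in air and at least 249-fold higher.

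The lists of cell cycle, ribosomal protein, tubulin and histone genes were not called. Of 42 genes of the cell cycle and DNA replication 6 rose and 4 fell (6 and 3 over the list alone, list adjusted p = 0.707), with the cyclin gene CYCD4-1 at 2.61 ± 0.27 and the kinesin gene KIN14M at -2.59 ± 0.30. Both calls were lost without aerobic replicate 1 (0.0609 and 0.0575), and that of CYCD4-1 without aerobic replicate 2 (0.063). Of 23 cytosolic ribosomal protein genes 2 rose and 0 fell. The rises were RPL27 and RPL7A-1, and both calls were lost without aerobic replicate 1 or 2. The median of the ribosomal list was 0.42 (camera, adjusted p = 0.0702). That list was called higher with no filter on mean level (0.0197), values under 5 set to 5 (0.0395), trend and robust eBayes (0.0369), without aerobic replicate 1 (0.0396) and without anoxic replicate 1 (0.00843). Of 10 tubulin genes 3 rose and 2 fell (adjusted p = 0.624), and of 5 histone genes 0 passed by limma, with 2 at an unadjusted p under 0.05 (list adjusted p = 0.258). The numbers for the ribosomal, tubulin and histone lists were the same when adjusted over the list alone. The histone gene with the smallest p, H2B.10, stood at 1.21 ± 0.36 and was called under quantile normalization (0.0259) and with a mean of at least 6 (0.0403).

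Among the 8 largest rises and 8 largest falls of called genes with a symbol, of those outside these lists and besides CHS, cap2 (LOC4331843) rose by 6.36 ± 0.27, and GER1 (LOC4344840), BURP2 and BURP17 of the BURP-domain genes, the beta-glucosidase gene BGLU30 and the IAA-amino acid hydrolase-like gene ILL3 fell. GER1 was at least 509-fold, BGLU30 at least 296-fold and BURP17 at least 94.9-fold lower, and BURP2 and ILL3 changed by -8.94 ± 0.51 and -8.11 ± 0.35 (adjusted p between 0.000568 and 0.00158 for these 5). BURP2 changed by -8.24 without anoxic replicate 2. Without anoxic replicate 1 it was at background in anoxia and at least 704-fold lower.

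None of the 3 marker lists of other tissues was called with all 4 arrays, and their numbers were the same when adjusted over the list alone. Of 5 tested photosynthesis genes, markers of leaf, PSAG fell by 1.40 on the log2 scale and 4 did not pass (list adjusted p = 0.912). Of 6 seed storage and maturation genes RAB21 rose by 1.46 ± 0.30 and 5 did not pass (adjusted p = 0.913). Of 3 root nutrient uptake genes PHT1-8 fell by 3.67 and NAS3 fell by 3.95 on the log2 scale (adjusted p = 0.0975 for the list, and 0.0379 without anoxic replicate 1). Without aerobic replicate 1 the calls of PSAG, RAB21 and PHT1-8 were lost (0.0534 to 0.1), likewise without aerobic replicate 2 (0.0555 to 0.143), and that of RAB21 without anoxic replicate 1 (0.0835). As signs of RNA quality, the difference between 3' and 5' control probe sets was 1.22 in aerobic and 1.64 in anoxic arrays for actin, 2.08 and 2.15 for Gapdh, and -0.86 and -1.33 for ubiquitin on the log2 scale. The 27 probe sets of hybridization spike-ins differed by -0.28 to 0.07 between groups.

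The counts rest on few arrays. Leaving out 1 aerobic array left 1894 (without replicate 1) or 1916 (without replicate 2) called probe sets, and leaving out 1 anoxic array left 4014 (without replicate 1) or 3916 (without replicate 2). With an estimated correlation, camera kept 0 of its 11 list calls (0 lists at an unadjusted p under 0.05), while fry, which does not compare a list with other genes, called 10 of these 11.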

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

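All tests of explanations below were chosen after the results they bear on had been seen.

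A control probe set outside the tests, for 5.8S ribosomal RNA, was at background in aerobic coleoptiles (log2 level 2.92) and at 5.45 in anoxic ones, a difference of 2.53, a signal outside the compared transcripts. Of the 187 control probe sets it alone was above background with both anoxic arrays at least 1 log2 unit above both aerobic arrays, and 0 were lower by as much; no test was run on control probe sets.

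Jasmonate genes were lower in anoxic coleoptiles, 21 of 24 of them. Leaf tissue left on the aerobic coleoptiles could have raised leaf markers in air. The median log2 change of the 5 tested photosynthesis genes was 0.32 (SD over genes 0.87), not a fall of at least 1. Without anoxic replicate 1 this median was -0.045. PSAG alone of the 5 was called, with a change of -1.40. PSAH (group means 4.18 and 4.66) and OEE3 (4.60 and 4.91) read close to background. The seedlings grew in the dark, and whether their leaves express these genes was not measured. The median therefore cannot decide, and leftover leaf tissue remains open. Wounding when the leaf was cut out, in aerobic samples only, may have contributed: the 6 tested WRKY genes, several of which respond to wounding, had a median of 0.18 (-0.38 without anoxic replicate 1) with an SD of 1.75, too wide to decide, so wounding and oxygen cannot be told apart here. Lack of oxygen, the difference that the design names, also remains open as untested, since the lipoxygenases that make the jasmonate precursor use oxygen.

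Small heat shock genes had a higher median in anoxic coleoptiles, though the list was not called. Anoxic replicate 1 read higher than replicate 2 for 11 of the 12 genes. The list's median difference between anoxic replicate 1 and 2 was 1.09. This lay above all 10000 random lists of 12 matched on level, the highest of which reached 0.82. The random lists hold unrelated genes, whereas genes of this list vary together (estimated correlation 0.462). Replicate 1 had also been seen to read higher beforehand, so the comparison is no separate evidence. A stress that differed between the anoxic samples would also raise other chaperones in replicate 1: the median difference of the 20 large chaperone and heat shock factor genes was 0.25, above 96.6% of random lists, narrowly short of the share set for it. The bound that would exclude it was rewritten once this value was known, so this remains open. HSP18.1, HSP24.1, HSP17.9A, HSP17.4, HSP18.6, HSP18.0, HSP26.2 and HSP17.7 read above both of their aerobic values on both anoxic arrays, and the other genes did not. Groups were separated in this way, in either direction, for 75.7% of all tested probe sets, so this carries little weight. An effect of anoxia remains open too.

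Of the tested probe sets 32.1% were called. A single scaling factor between the groups would leave the correlation between arrays as it is. The highest r between an aerobic and an anoxic array was 0.698, against 0.968 and 0.973 within groups. This test was chosen after these correlations were known. The even balance of calls in each direction decides nothing here, since the deposited values were normalized. Poorer RNA in the anoxic samples would widen the 3' to 5' difference of the control transcripts. The median widening was 0.064 (SD 0.45), the value of Gapdh, with actin at 0.42 and ubiquitin at -0.47. Ubiquitin read brighter near its 5' end in both groups. Actin probe sets outside this test changed by -0.33 and -0.48 near the 3' end and by -0.81 near the 5' end. So few transcripts, going both ways, cannot decide how far poorer RNA took part. The correlations argue against a single scaling factor as the whole cause. Whether total mRNA per cell differed was not tested, and normalized arrays do not show it.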

How the results depend on the processing

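The crossed pairing of replicates was chosen after the data were seen, and the other settings were planned. None of the alternatives reversed a called gene among those named or a called list. Of lists not called, 10 changed the sign of their median under an alternative, and camera and fry gave opposite directions for 4 (large chaperones, WRKY, photosynthesis and sugar transporters); AOX1A changed sign too. Calls shared with the main setting had the same direction. Against 6036 probe sets called (3015 higher, 3021 lower), 1709 were called with no filter on mean level (738 higher, 971 lower; 1604 shared), 3829 with a mean of at least 6 (1934 and 1895; fewer, 11354, were tested), 3348 with values under 5 set to 5 (1600 and 1748), 2318 with treat (913 and 1405), which asks for more than the fold threshold, and 732 with limma without moderation of the variance (290 and 442). The cause of the drop with no filter was not tested. Leaving out 1 array, where the lone array is assumed to vary like the other group, leaves 1 residual degree of freedom and gave 1894 to 4014 calls (663 to 1914 higher, 1035 to 2225 lower). The other settings kept these counts within 1.5 times. The sample titles link same-numbered arrays only by the number, and whether they were handled together is not known. The correlation of their deviations was -0.142 over 18826 probe sets. The replicate block gave 5556 calls and ended those of AMT1;1 and SWEET11, and the crossed pairing gave 6467. Lists up (2) and down (9) became 0 and 0 by camera with an estimated correlation, which has 2 residual degrees of freedom here, 1 and 4 with a mean of at least 6, 1 and 7 with quantile normalization, 3 and 14 by fry (7 lists beyond the 11), and 1 to 3 and 8 to 11 with 1 array left out; the cause was not tested. The fermentation, xyloglucan and cellulose, jasmonate and metallothionein calls were lost only with the estimated correlation. That correlation lay below the preset 0.01 for the fermentation (-0.408), xyloglucan and cellulose (-0.0192) and auxin (-0.0219) lists. It was also below 0.01 for the aquaporin (-0.0264) and endoplasmic reticulum folding (-0.0143) lists. A correlation above the preset therefore did not end these calls. For the other called lists it was above 0.01, up to 0.403 for jasmonate. The small heat shock list was called with the replicate block (adjusted p = 0.0361; 0.00272 to 0.784 over its alternatives), as was the ERF list (0.0361; 0.0274 to 0.784). Of 104 named genes 55 lost their call with no filter, 73 without moderation, 21 with values under 5 set to 5, 42 without each aerobic array, 17 without anoxic replicate 1 and 9 without anoxic replicate 2. Background limits dim genes, with a group at background in 1574 called probe sets.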

Other observations

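Genes of the same list did not always move together. As 1958 of 12291 tested genes rose and 2212 fell, lists of unrelated genes would often hold both directions too. The count that follows was not compared with such lists, so it shows nothing particular to these lists. Of 36 lists with a tested gene, 19 held genes called in both directions, as with the hexokinases (HXK7 higher, HXK5 and HXK6 lower), the beta-tubulins (TUBB7 at 1.37 and TUBB3 at 1.21 against TUBB8 at -1.32 and TUBB6 at -1.04) and the glutathione transferases. Leaving out any 1 of the 4 arrays ended the calls of TUBB8 (adjusted p from 0.0515 to 0.0685) and TUBB6 (0.0528 to 0.123), and each array but anoxic replicate 2 ended those of TUBB7 (0.0565 to 0.0717) and TUBB3 (0.0503 to 0.0825).

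Gene families were then formed, after the lists had been seen, from the letters that open a gene's symbol, and the 28 families with at least 8 tested genes were compared by camera with a preset correlation. JAZ (11 of 11 lower, adjusted p = 6.08e-05) and IAA genes (12 of 20 lower, 0 higher, adjusted p = 0.0164) were shifted down, and both belong to lists described above; adjusted p = 0.64 for each with an estimated correlation. Both kept their calls without any 1 array (adjusted p of 0.0312 or less). The next 9 families did not pass: BGLU (10 of 18 lower, 3 higher), CML (8 of 18 lower), HAK (5 of 12 lower, 1 higher), HOX (6 of 15 lower, 1 higher), PDIL (4 of 9 lower) and RPL (3 of 13 higher) with adjusted p = 0.0545, GT (4 of 9 lower) and HSP (4 of 15 higher) with 0.0554, and CIPK (8 of 20 lower, 3 higher) with 0.0573. RPL and HSP leaned up and the other 7 down. Without anoxic replicate 1 the CML, HAK (0.0409 for each) and RPL (0.0261) families were called, and without anoxic replicate 2 PDIL (0.035) and HSP (0.00363). Of the BGLU genes, which encode beta-glucosidases, BGLU30 fell at least 296-fold and BGLU12 had a log2 change of -6.43 ± 0.17 (SE). Of the 152 called members of the 28 families, 102 and 98 lost their call without aerobic replicate 1 and 2, and 47 and 51 without anoxic replicate 1 and 2, so the counts per family rest on all 4 arrays.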
